A study of Mus musculus with 11 samples.

How the data were processed

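Gene expression was measured in trigeminal ganglia, the sensory ganglia of the face, of mouse embryos at embryonic day 13.5. Embryos were wild-type, heterozygous or homozygous for a knockout of Pou4f1, the gene of the POU-domain transcription factor Brn3a. Per the labels, each array held RNA from a pool of 10 to 12 ganglia of 1 genotype. The 11 arrays were of 2 Affymetrix types with different probe sets, U74Av2 (6 arrays, 2 per genotype) and U74Bv2 (5 arrays, of which 2 were knockout, 2 heterozygote and 1 wild-type). Whether the same RNA pools went on both array types is not given in the sources used here. No label ties an array to single animals beyond the pool, so the p-values measure the spread between these arrays.

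The deposited values are microarray intensities, 1 signal per probe set on a linear scale, made with MAS5 per the submitters' processing notes. The MAS5 version and the scaling target are not given in the sources used here. The 2% trimmed mean of the deposited signals lay between 500.26 and 500.29 on the U74Av2 arrays and between 497.61 and 498.38 on the U74Bv2 arrays, so no further scaling was applied. Detection calls were not used here, so a low signal cannot be called absent. The number of arrays limits the precision of every value. The U74Av2 table held 12488 probe sets, of which 66 were manufacturer's controls, and the U74Bv2 table held 12411 with 0 such controls.

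Gene symbols came from the platform annotation and were updated through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6, used for names only. On U74Av2, 10855 probe sets had 1 symbol, 396 had several and 1237 had none. On U74Bv2 these numbers were 10581, 178 and 1652. The Entrez identifier matched for 10839 and 10550 probe sets, and 0 symbols changed. A probe set with several symbols was not named. A probe set whose name ends in _f_at, _r_at, _s_at, _i_at or _g_at was designed with relaxed rules or matches several transcripts, which is stated for the genes concerned.

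The analysis used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with matplotlib 3.10.9 for the plots. Signals were taken as log2(signal + pseudocount), with a pseudocount of 50.0 on U74Av2 and 49.8 on U74Bv2, 0.1 of the mean trimmed mean. Fold changes are on this scale and understate the change of dim probe sets. Controls were left out, and so were probe sets whose mean log2 value was at or below the 40th percentile, which left 7453 probe sets of 5663 named genes on U74Av2 and 7446 of 5152 on U74Bv2. A limma model with genotype as its factor was fitted to all arrays of a type, followed by eBayes with an intensity trend. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison and array type, two-sided. The wild-type U74Bv2 array stood alone, and its spread was assumed to be like that of the other genotypes. A further fit set knockout against all arrays that were not knockout.

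The following choices were made before the data were examined. The text names, per comparison and array type, the 12 genes with the largest rise and the 12 with the largest fall among called probe sets with 1 symbol and no overlap between the genotypes' arrays, with the brightest probe set taken for a gene. Where fewer than 10 passed, the 5 largest differences at an unadjusted p under 0.01 are given as values. Pou4f1 is always given. From each of the gene lists, called members up to 6 are named, or otherwise the 3 brightest as values. The lists covered neuronal functions, neurogenesis, cell states and the other cell types that a dissection could hold, and 22 of them were tested for a shift with limma's camera at an inter-gene correlation of 0.01, with 1 probe set per gene. A list needed 5 measured genes. With an estimated correlation in its place, camera uses the few residual degrees of freedom of the fit, so a list can scarcely pass. Several neuronal lists contain genes known from published work on this mutant, possibly from these arrays, so those lists are not independent evidence of their direction.

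On simulated U74Av2 data for knockout against wild-type, with 7453 probe sets, the fit recovered 23.6% of seeded changes of log2 size 1, 93.4% of size 2 and 99.1% of size 3, with a mean of 9.60 false calls. On simulated U74Bv2 data for the same comparison, with 7446 probe sets, it recovered 51.3%, 97.3% and 100%, with a mean of 8.40 false calls. On each array type 335, 335 and 330 changes of sizes 1, 2 and 3 were seeded over 5 runs. That many changes ease the adjusted threshold, so recovery would be lower where few transcripts change. The replicate numbers 1 and 2 in the labels were shared between genotypes. The fit without them was the main one, and a fit with the number as a block was an alternative. On U74Bv2 the block left fewer residual degrees of freedom than the main fit, and the lone wild-type array was a number 1 array. Counts with the block are therefore weak there. The block in the fit of knockout against all other arrays was added after the controls were seen. On U74Av2 the control probe sets separated the numbers, so values within each number are also given. Other alternatives changed the pseudocount, the normalization, the filter, the variance model, the arrays in the fit, the test, the correlation between genes and the probe sets per gene, and left out each array in turn.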

Results

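Trigeminal ganglia were taken at embryonic day 13.5, when according to the design text sensory axon growth is already disturbed in the mutant and most of the later neuronal death lies ahead. Brn3a, encoded by Pou4f1, is a homeodomain transcription factor of sensory neurons. The study asked which transcripts depend on it. Each U74Av2 value rests on 2 arrays per genotype. Each U74Bv2 value rests on 2 knockout, 2 heterozygote and 1 wild-type array.

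Pou4f1 itself was measured by 1 tested probe set, on U74Bv2. Its signal was 3313 in the wild-type array, 2196 and 3570 in the heterozygotes, and 550 and 904 in the knockouts. The transcript was 4.45-fold lower in knockout than in wild-type ganglia (log2 difference -2.15 ± 0.34 SE, limma adjusted p = 0.0245) and 3.77-fold lower than in heterozygotes (adjusted p = 0.0111). The heterozygote differed from wild-type by -0.24 ± 0.34 (adjusted p = 1.00), within the error. Which part of the gene this probe set covers, relative to the deleted part, is not given in the sources used here. Whether the fall is that of the deleted part is therefore open. The signal did follow the genotype labels, with both knockout arrays below all others. The call against wild-type was lost without an intensity trend and without the filter on dim probe sets, and the call against heterozygotes without the filter.

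On U74Av2, several transcripts with low signals in wild-type ganglia rose in knockout. Gata3, a zinc-finger transcription factor, rose from a signal of 73.2 ± 17.0 (SD, n = 2) to 2380 ± 204, a 19.8-fold change (log2 4.31 ± 0.26 SE, adjusted p = 0.00246). The neuropeptide somatostatin (Sst) rose 16.4-fold, from 59.6 to 1752 (log2 4.04 ± 0.24). The transcription factor Tfap2b rose 15.1-fold (log2 3.91 ± 0.35), the calcium-binding protein calretinin (Calb2) 10.4-fold (3.38 ± 0.39) and the growth factor Vegfd 7.08-fold (2.82 ± 0.31). Msc, a bHLH transcription factor, rose 6.92-fold, the small GTPase Rab3b 6.06-fold, and the serotonin-gated channel subunit Htr3a 5.08-fold, from 952 to 5016.

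The transcripts lost on U74Av2 were led by Rgs10, a regulator of G-protein signalling, which fell from 1275 ± 264 to 84.9 ± 27.4 (log2 -3.30 ± 0.26 SE, adjusted p = 0.00807). The actin-binding protein advillin (Avil, log2 -2.72), Eepd1 (-2.47), the homeobox factor Hmx1 (-2.23), Rasa4, which restrains Ras (-2.20), and the potassium channel Kcna1 (-2.14) fell with it. The transcription factor Runx1 (-2.06) fell from 731 to 138 and the neuropeptide galanin (Gal, -2.01) from 3952 to 945. The adaptor Shc1 (-1.80) and Olfm1 (-1.67) also fell, the last from a probe set that can match related transcripts. A further Rgs10 probe set, of a family type, also fell (-2.83).

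In all, 19 of 7453 probe sets (18 genes) were called on U74Av2, 8 higher and 11 lower in knockout, and 381 had an unadjusted p under 0.05 where 373 were expected by chance. The main fit counts differences between array numbers, found in 1820 probe sets, as spread. This raises the p-values of such probe sets, so the number expected by chance is not a fair measure here. No called probe set overlapped between the genotypes' arrays. With the replicate number as a block 130 were called, 43 up and 87 down, among them all 19. The changes within number 1 and within number 2 were 4.53 and 4.08 for Gata3 and -3.30 and -3.29 for Rgs10. That each named gene changed the same way within both numbers follows from the lack of overlap between genotypes that the naming rule asks for. Without knockout array 1 no probe set was called, with 5 called without knockout array 2, 4 without wild-type array 1 and 2 without wild-type array 2. All 16 of the 19 that could still be tested without knockout array 1 kept their sign, which the lack of overlap also makes certain.

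**Figure D1:**
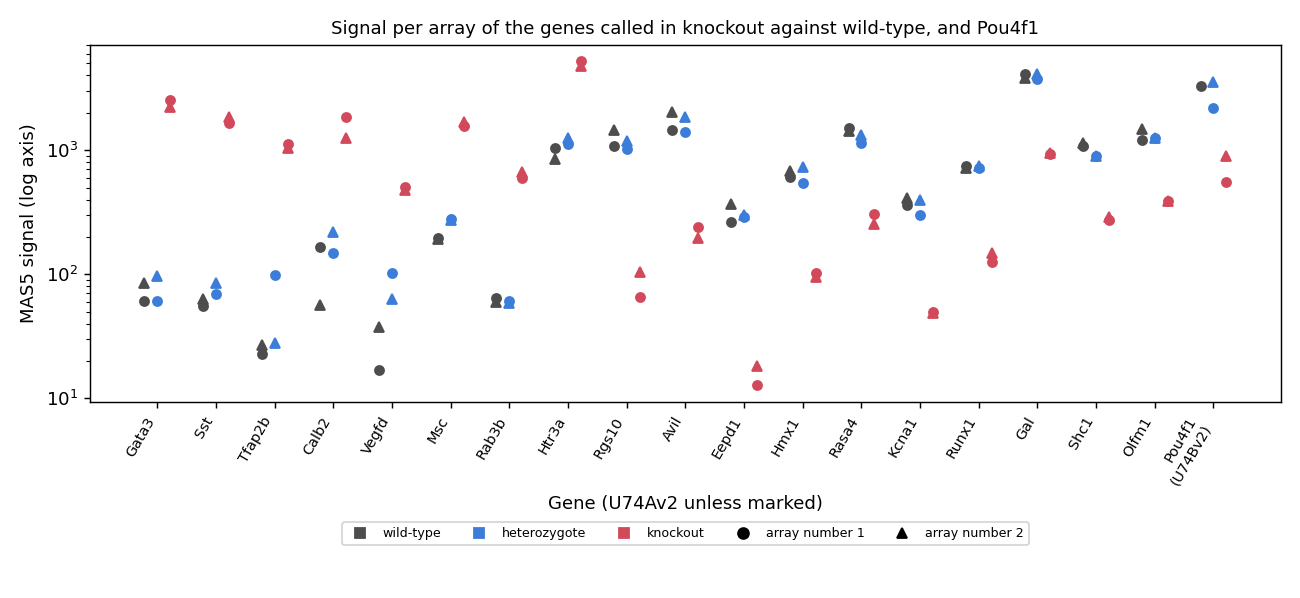
MAS5 signal per array (log axis) for the 18 genes called in knockout against wild-type on U74Av2 and for Pou4f1 on U74Bv2; colours are genotypes and marker shapes are array numbers. For every gene the knockout points lie apart from the wild-type points, and for Gata3 the 2 wild-type arrays average 73.2 against 2380 in knockout.

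Transcription factors moved in both directions. Of 18 sensory neuron transcription factors measured on U74Av2, 2 rose (Gata3 and Tfap2b), 2 fell (Runx1 and Hmx1) and 14 did not pass. Adjusted over the list alone, 2 rose and 3 fell, and the list as a whole did not shift (camera adjusted p = 0.743). Of 23 neurogenic bHLH and Notch pathway genes Msc rose and 22 did not pass (3 up and 1 down adjusted over the list alone, camera adjusted p = 0.530). Of 11 Hox genes none was called (1 down adjusted over the list alone, camera adjusted p = 0.552). Hoxd1 had a difference of -2.50 ± 0.45 SE (adjusted p = 0.147, and 0.0151 with the block). With the block, 3 sensory neuron transcription factors rose and 3 fell, 4 neurogenic genes rose and 1 fell, and 1 Hox gene fell.

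Ion channel and synaptic vesicle genes lay lower at the preset correlation, and other neuronal signalling lists did not. Of 23 voltage-gated and sensory ion channels, Htr3a rose, Kcna1 fell and 21 did not pass (1 up and 4 down adjusted over the list alone). The list lay lower in knockout (mean log2 difference -0.32, median -0.08, camera adjusted p = 0.00411, and adjusted p = 0.208 with an estimated correlation). Of 17 synaptic vesicle and release genes none was called, 2 fell adjusted over the list alone and 3 fell with the block. Their median difference was -0.26 (camera adjusted p = 0.00529, and adjusted p = 0.208 with an estimated correlation), with Sncg, from a family probe set, at -0.69 ± 0.35 SE and Vamp2 at -0.31 ± 0.24. Among 12 neuropeptides Sst rose and Gal fell (3 up and 2 down adjusted over the list alone), with no shift of the list (camera adjusted p = 0.196). Of 11 calcium-binding proteins Calb2 rose and 10 did not pass (1 up adjusted over the list alone). Their median was 0.35 higher (camera adjusted p = 0.0114, and adjusted p = 0.224 with an estimated correlation). With the block, 1 ion channel rose and 3 fell, 2 neuropeptides rose and 2 fell, and 2 calcium-binding proteins rose. These neuronal lists hold genes known from published work on this mutant and are not independent evidence.

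Genes of DNA replication and mitosis were slightly higher in knockout on U74Av2. Of 40 measured cell cycle genes 38 had a positive difference, with a median of 0.37 (1.29-fold, camera adjusted p = 7.07e-09, 3.30e-08 with the block, and adjusted p = 0.208 with an estimated correlation). By fry, another list test of limma, the cell cycle list did not pass (fry adjusted p = 0.0521). No member was called, over all probe sets or adjusted over the list alone, and 1 was higher with the block (Ccnd1, 0.94, adjusted p = 0.0430). The brightest members were Stmn1 (0.74 ± 0.27 SE), which is also a neuronal microtubule regulator, Bub3 (0.22 ± 0.21) and Ccnb2 (0.33 ± 0.30). Mesenchyme and connective tissue markers had a median of 0.26 over 26 genes (camera adjusted p = 0.00332, and adjusted p = 0.208 with an estimated correlation), with none called and with the bright members Igf2 at 0.08, Dlk1 at -0.27 and Col1a2 at 0.02, the Igf2 and Col1a2 probe sets being of relaxed design. Without knockout array 2, cell cycle was the 1 list left past the threshold of the 5.

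Apart from the connective tissue list, no list of markers of other cells passed on U74Av2. Of 16 Schwann and satellite glia markers Kcna1, which also stands among the channels, fell and 15 did not pass (1 down adjusted over the list alone), with a median of 0.05 (camera adjusted p = 0.749). None was called among 14 endothelial markers (median -0.07), 11 macrophage and immune markers (-0.04), 13 skeletal muscle markers (-0.01), 12 red blood cell markers (0.15) or 6 cartilage and bone markers (0.37, camera adjusted p = 0.136). None of 7 central nervous system markers was called, 1 fell adjusted over the list alone, and Meis2 stood at -1.74 ± 0.28 SE (adjusted p = 0.111, and 0.0160 with the block, where it was called). Of 36 neuronal cytoskeleton genes Avil fell, over all probe sets and adjusted over the list alone, with a list median of 0.12 (camera adjusted p = 0.749). No member was called, over all probe sets or adjusted over the list alone, among 6 neurotrophin and GDNF family receptors (median -0.35, Gfra3 at -0.67 ± 0.22), 26 axon guidance genes (-0.05), 16 apoptosis regulators (-0.03), 11 p53 targets (0.02) or 21 immediate early and heat shock genes (0.03). With the block, 2 glia markers and 3 neuronal cytoskeleton genes fell, 1 axon guidance gene rose and 3 fell, and 1 p53 target (Gadd45a) rose and 1 (Plk2) fell. None passed with the block among neurotrophin receptors, apoptosis regulators or immediate early genes.

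**Figure D2:**
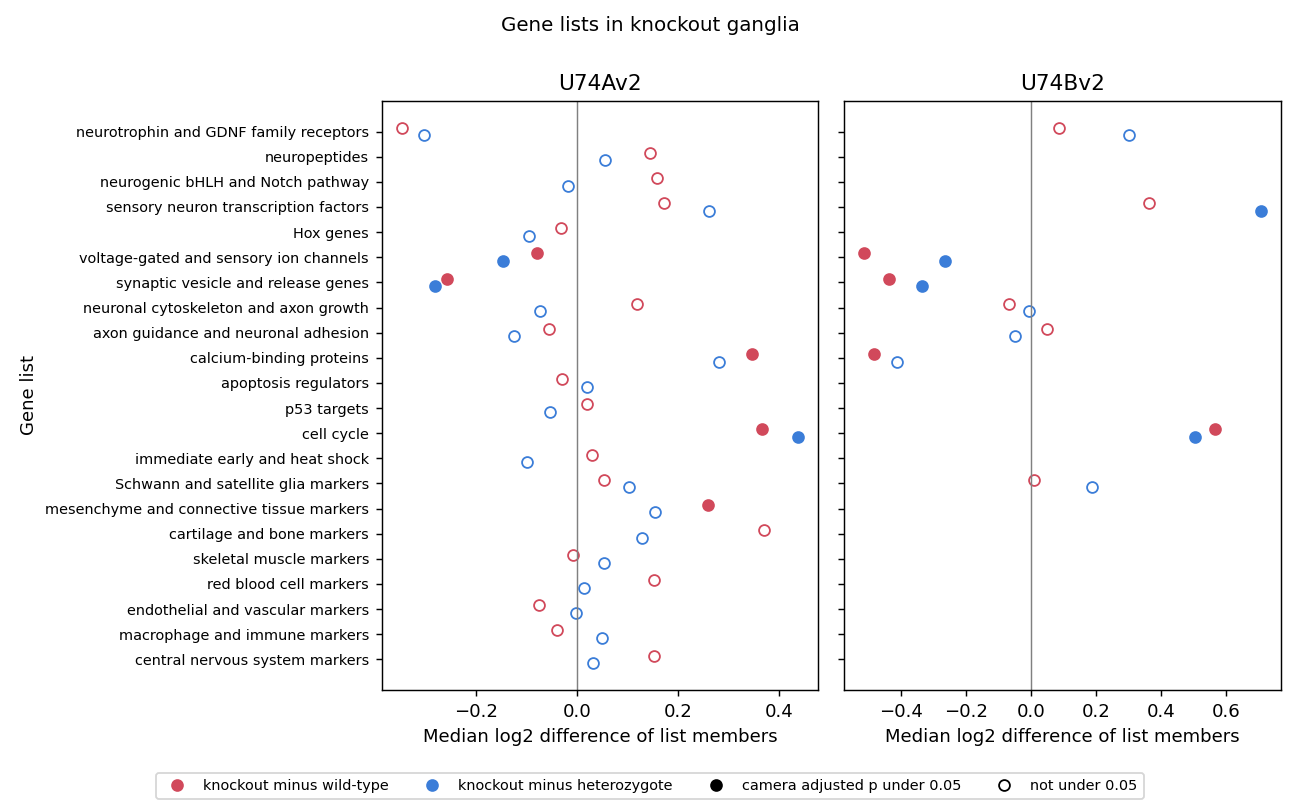
Median log2 difference of the members of each gene list in knockout against wild-type (red) and against heterozygote (blue) on each array type; filled points have a camera adjusted p under 0.05 at the preset correlation, and lists with fewer than 5 measured genes are not drawn. Cell cycle lies to the right (medians 0.37 and 0.44 on U74Av2), and ion channels and synaptic vesicle genes lie to the left on both array types.

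The control probe sets on U74Av2 differed between array numbers and genotypes. The 3 probe sets for 18S ribosomal RNA had a geometric mean signal of 5173, 6745 and 12803 in the number 1 arrays of wild-type, heterozygote and knockout, and of 511, 518 and 974 in the number 2 arrays. Number 1 was thus 10.1-, 13.0- and 13.2-fold above number 2. Within the numbers, knockout stood 2.48-fold and 1.90-fold above wild-type. The 9 bacterial spike-in probe sets had a geometric mean signal of 2460, 9999 and 7742 in number 1 and 1733, 2037 and 2821 in number 2. The ratio of 3' to 5' probe sets lay between 1.08 and 1.31 for actin and between 0.872 and 1.07 for Gapdh.

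**Figure D3:**
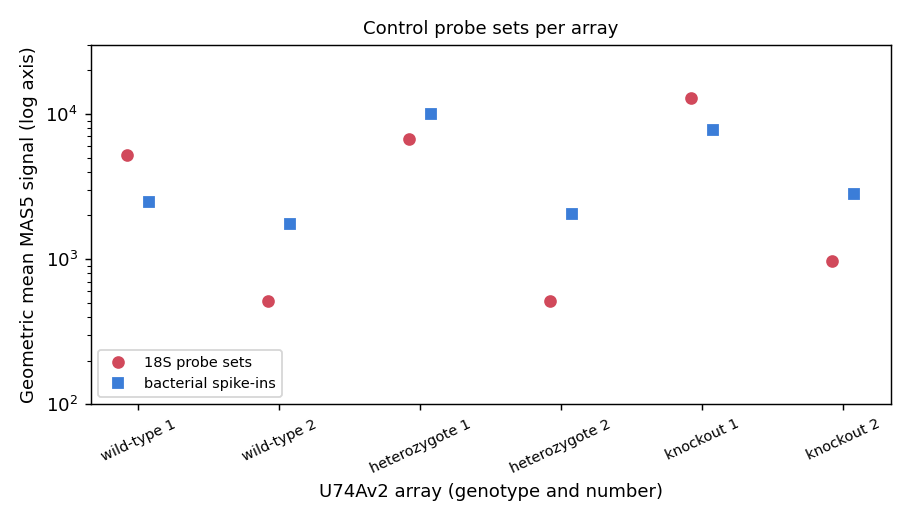
Geometric mean MAS5 signal (log axis) of the 18S ribosomal RNA probe sets (circles) and the bacterial spike-in probe sets (squares) on each U74Av2 array. The 18S signal is 5173 to 12803 in the number 1 arrays and 511 to 974 in the number 2 arrays.

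On U74Bv2, which holds mostly other genes, Gata3 (21.3-fold, log2 4.42 ± 0.39 SE, adjusted p = 0.00226) and Tfap2b (15.7-fold, 3.97 ± 0.26, adjusted p = 5.84e-04) again led the rise in knockout against wild-type. They were followed by Caly (log2 2.54), the LIM-domain cofactor Lmcd1 (2.46), the homeobox factor Irx1 (2.44, from a family probe set, which can match related transcripts), Fstl5 (1.94), Shisa2 (1.87) and the forkhead factor Foxf1 (1.86). The sodium channel Scn7a fell by 2.78 ± 0.20, from 3230 to 426. The small GTPase Diras2 (-2.55), Fam102b (-2.37), Runx1 (-2.33), Rgs7bp, which anchors G-protein regulators at the membrane (-2.28), and the phosphatase Ptpn3 (-2.28) also fell. Further falls were those of Mtus2 (-2.25), Bves (-2.25), Plcxd2 (-2.23), Sytl2 (-2.19) and the calcium-binding protein Cabp1 (-2.17).

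Of 7446 probe sets on U74Bv2, 104 (90 genes) were called in knockout against wild-type, 35 higher and 69 lower, and 834 had an unadjusted p under 0.05. For 10 of the 104 the heterozygote lay nearer to the knockout, so that these calls rest on the 1 wild-type array. They include Gbf1 (2.20), Slc37a1 (1.93), Cnot2 (1.90), Wars2 (1.82) and Caly. Heterozygote minus wild-type was 1.80 for Gbf1, 1.68 for Slc37a1, 1.54 for Cnot2, 1.89 for Wars2 and 1.67 for Caly. The Gbf1 and Cnot2 probe sets are of a relaxed design (_r_at), and on U74Av2 these genes stood at -0.03 and 0.09. A further Slc37a1 probe set on U74Bv2 was not called (182 in wild-type, 200 and 199 in heterozygote, 201 and 180 in knockout), nor was a further one for Gbf1 (254, then 236 and 251, then 391 and 227). The count was 40 without an intensity trend, 21 without the filter, 174 without heterozygote array 1 and 178 without knockout array 1.

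Among 8 sensory neuron transcription factors on U74Bv2, Gata3, Tfap2b and Irx1 rose and Runx1 and Pou4f1 fell, the same 3 and 2 adjusted over the list alone, while the list did not shift (camera adjusted p = 0.112). Of 15 ion channels Scn7a and Kcna1 (-1.87 ± 0.29 SE) fell, 5 adjusted over the list alone, and the list lay lower (median -0.51, camera adjusted p = 0.00320, and adjusted p = 0.318 with an estimated correlation). Of 16 synaptic vesicle genes none was called (1 up and 3 down adjusted over the list alone, and likewise with the block), with a median of -0.44 (camera adjusted p = 0.00706, and adjusted p = 0.318 with an estimated correlation). Of 6 calcium-binding proteins Nell2 rose (1.26 ± 0.23, incomplete probe set), Cabp1 fell, and the list lay lower (median -0.48, 1 up and 2 down adjusted over the list alone, camera adjusted p = 0.0199, and adjusted p = 0.364 with an estimated correlation), opposite to the members measured on U74Av2. The 5 cell cycle genes had a median of 0.56 (none called, 1 up adjusted over the list alone and 1 up with the block, camera adjusted p = 0.00480, and adjusted p = 0.318 with an estimated correlation).

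Axon guidance receptors on U74Bv2 went both ways. The neuropilin Nrp2 rose (1.80 ± 0.21 SE), the ephrin receptor Epha7 (-1.74 ± 0.23) and the adhesion molecule Cntn2 (-1.12 ± 0.22) fell, and 25 of 28 genes did not pass, with 4 up and 3 down adjusted over the list alone (camera adjusted p = 0.853). The low-affinity neurotrophin receptor Ngfr fell (-1.31 ± 0.22, adjusted p = 0.0319), as 1 of 5 neurotrophin and GDNF receptors (1 up and 1 down adjusted over the list alone). The bHLH factor Neurod1 rose (1.55 ± 0.28), from an incomplete probe set, as 1 of 4 neurogenic genes, also adjusted over the list alone. Of 22 neuronal cytoskeleton genes none was called or passed adjusted over the list alone (median -0.07), and 1 rose with the block. Of 9 glia markers Ngfr and Kcna1, both also on neuronal lists, fell, likewise 2 adjusted over the list alone (camera adjusted p = 0.173).

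Against heterozygotes the knockout showed largely the same leading genes. On U74Av2 Gata3 (log2 4.25 ± 0.26 SE), Sst (3.83), Tfap2b (3.38), Rab3b (2.63), Msc (2.37) and Htr3a (2.04) rose. Rgs10 (-3.10), Avil (-2.64), Eepd1 (-2.40), Hmx1 (-2.20), Runx1 (-2.06), Gal (3.99-fold) and Rasa4 (-1.97) fell. These made up 14 called probe sets, 6 up and 8 down (391 at an unadjusted p under 0.05), and 129 with the block. All 14 were also called against wild-type with the same sign, where 0.0182 would be shared by independent lists. Simulations of unchanged genotypes with these arrays gave fewer on average, but with no genotype effect little is called at all. The knockout arrays are common to both comparisons and part of the sharing may come from them. How large that part is was not measured. Without knockout array 1 none was called, and 5 were called without knockout array 2, 3 without heterozygote array 1 and 2 without heterozygote array 2.

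On U74Bv2 the gains over heterozygotes were led by Tfap2b (log2 3.87 ± 0.21 SE), Gata3 (3.50), Lmtk2 (2.66), Irx1 (2.63) and Lmcd1 (2.11). The adhesion molecule Chl1 (1.73), Foxf1 (1.72), the glutamate receptor subunit Gria3 (1.69), Neurod1 (1.67), Fstl5 (1.67), Nell2 (1.56) and the globin Cygb (1.52) followed. Scn7a (-3.03 ± 0.17), Diras2 (-2.37), Fam102b (-2.35), Lyrm9 (-2.33), Runx1 (-2.32), Mtus2 (-2.30), Rgs7bp (-2.20), Ptpn3 (-2.04), Kcna1 (-1.99), Plcxd2 (-1.98) and the axonal protein Cntnap1 (-1.83) fell. A further, brighter Lyrm9 probe set fell less, with signals of 1010 and 1202 in heterozygotes and 809 and 782 in knockouts. Lmtk2 had a signal of 974 in the wild-type array, 289 and 240 in heterozygotes, and 1717 and 2175 in knockouts. In all 127 probe sets were called, 38 up and 89 down (720 at an unadjusted p under 0.05), and 83 of them were also called against wild-type with the same sign. Independent lists would share 1.00, but both comparisons use the same knockout arrays. Simulations of unchanged genotypes gave a mean of 0.08, but with no genotype effect little is called at all. How much of the sharing comes from the common arrays was therefore not measured. The count was 54 without the filter and 81 without an intensity trend.

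Against heterozygotes, cell cycle genes on U74Av2 again lay higher (37 of 40 positive, median 0.44, camera adjusted p = 7.20e-12, and adjusted p = 0.175 with an estimated correlation). Ion channels (median -0.15) and synaptic vesicle genes (median -0.28) lay lower, each with a camera adjusted p of 6.76e-04, and adjusted p = 0.175 with an estimated correlation. On U74Bv2 the sensory neuron transcription factors lay higher (median 0.71, camera adjusted p = 0.00822, and adjusted p = 0.322 with an estimated correlation) with Gata3, Tfap2b and Irx1 up and Runx1 and Pou4f1 down. Ion channels lay lower there (adjusted p = 0.00236), with Scn7a, Kcna1 and Cacna2d1 down, as did synaptic vesicle genes (adjusted p = 0.00822), with Vamp1 down (-1.60) and Cplx2 up (1.07), and cell cycle genes lay higher (adjusted p = 0.0144). These 3 lists too had an adjusted p of 0.322 with an estimated correlation. The count of shifted lists on U74Av2 was 5 without heterozygote array 1 or knockout array 1 and 1 without knockout array 2, and on U74Bv2 2 without heterozygote array 1 and 1 without knockout array 2. Of the axon guidance genes Chl1, Nrp2 (1.39) and Sema6a (1.12) rose while Epha7 (-1.53) and Cntn2 (-1.17) fell. Ngfr (-1.52) and the cell death gene Hrk (-0.90) fell.

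Heterozygotes showed no called probe set against wild-type on either array type with limma. On U74Av2, 52 probe sets had an unadjusted p under 0.05, 373 being expected by chance, and on U74Bv2 283 had, with 372 expected. The U74Av2 fit counts differences between array numbers as spread, which raises p-values, so its low count does not show that heterozygotes were unchanged. The largest U74Av2 differences at an unadjusted p under 0.01 were those of Traip (-1.92 ± 0.22 SE, adjusted p = 0.437), Slc25a53 (-1.87 ± 0.35), H2-D1 (1.47 ± 0.33), Mob2 (-1.26 ± 0.29) and Rps4x (-1.17 ± 0.31), the last 3 from probe sets of relaxed design. On U74Bv2 they were those of Med1 (2.29 ± 0.66), Rbck1 (1.99 ± 0.34), Wars2 (1.89 ± 0.24, adjusted p = 0.197), Gbf1 (1.80 ± 0.29) and Lmtk2 (-1.71 ± 0.24), with those of Med1, Rbck1 and Gbf1 from relaxed or incomplete probe sets. Further probe sets stood at 0.18 for H2-D1, 0.19 for Rps4x, 0.49 for Mob2 on U74Bv2 and -0.15 for Med1, and those of Rbck1 lay on either side of 0. No gene list shifted on either array type in the main fit. The neuronal cytoskeleton list on U74Av2 lay near the threshold (median 0.12 higher in heterozygotes, camera adjusted p = 0.0509). It passed with the block (camera adjusted p = 0.0206) but not with an estimated correlation (camera adjusted p = 0.578). The fit with the block called 0 on U74Av2 and 7 on U74Bv2, and on U74Bv2 10 were called without knockout array 1, 1 without knockout array 2 and 2 without heterozygote array 2. Without heterozygote array 1, 4 lists passed on U74Av2.

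The 3 genotypes allow the heterozygote to be placed between the others. Over the 19 probe sets called on U74Av2 the heterozygote had moved by a median of 0.13 in the knockout's direction, with 17 of 19 moving that way, against a median knockout change of 2.60. Heterozygotes simulated with no change, sharing the wild-type arrays, gave medians that averaged 0.03, with 95% of them between -0.07 and 0.17, but that spread included the difference between array numbers. With the number kept apart, in simulations chosen after the result was seen, they averaged 0.01, with 95% between -0.08 and 0.10, and 28.6% to 73.0% of called probe sets moved in the knockout's direction against 89.5% observed. The observed shift thus lay outside the range for an unchanged heterozygote, in simulations that took probe sets as independent. The heterozygote's share of the change was largest for Vegfd (0.276) and Calb2 (0.179), and was 0.0130 for Gata3 and 0.0527 for Sst. Over all tested probe sets the covariance of the differences from wild-type was 0.0309 on U74Av2, against 0.0518 simulated for unchanged genotypes, and 0.0212 with the number kept apart (upper end of the 95% range 0.0227), which the observed value exceeded. Differences within opposite numbers, which share no array, had covariances of 0.00807 and 0.00884. On U74Bv2, with its 1 wild-type array, it was 0.0829 against 0.0588 simulated (95% of simulations between 0.0563 and 0.0618).

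Knockout was also set against all other arrays together. On U74Av2 this called 65 probe sets, 22 up and 43 down (266 with the block), including all 19 called against wild-type, and the count was 17 without knockout array 1, 27 without knockout array 2, 42 without heterozygote array 1, 31 without heterozygote array 2, 31 without wild-type array 1 and 33 without wild-type array 2. Besides the genes above, the neurogenic factor Neurod4 (log2 2.37 ± 0.34 SE), Zbtb16 (2.02), the gap junction protein Gja1 (1.89) and Serpini1 (1.62) rose, the Zbtb16 and Gja1 probe sets being of relaxed design. The neuropeptide Y receptor Npy1r (-2.53 ± 0.36), Hoxd1 (-2.47), the zinc-finger factor Bnc1 (-2.16) and the neuropeptide Adcyap1 (-2.09) fell. On U74Bv2 218 were called, 72 up and 146 down, with the glutamate transporter Slc1a3 up (1.47) and Zdhhc22 down (-2.76 ± 0.53), and the count was 112 without heterozygote array 1, 125 without knockout array 1, 115 without knockout array 2 and 130 without the wild-type array.

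Genes with probe sets on both array types were compared directly. Gata3, Tfap2b, Runx1 and Kcna1 were called on both, in the same direction. Of 17 genes called on at least 1 type, 14 had the same sign on both, among them Scn7a (-1.47 and -2.78), Hivep2 (-1.31 and -1.63), Epha7 (-1.18 and -1.74) and Neurod1 (1.28 and 1.55). Gbf1, Igf1 and Ctnnbip1 were called on U74Bv2 with differences of -0.03, 0.08 and -0.07 on U74Av2. Hivep2, Igf1 and Ctnnbip1 were singled out after their values were seen. Across all 1121 genes tested on both, 57.5% had the same sign, with Pearson's r = 0.50 and Spearman's rho = 0.287 (two-sided permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Without the 17 genes r was 0.311. Genes are not independent replicates, and the array types may share RNA pools.

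**Figure D4:**
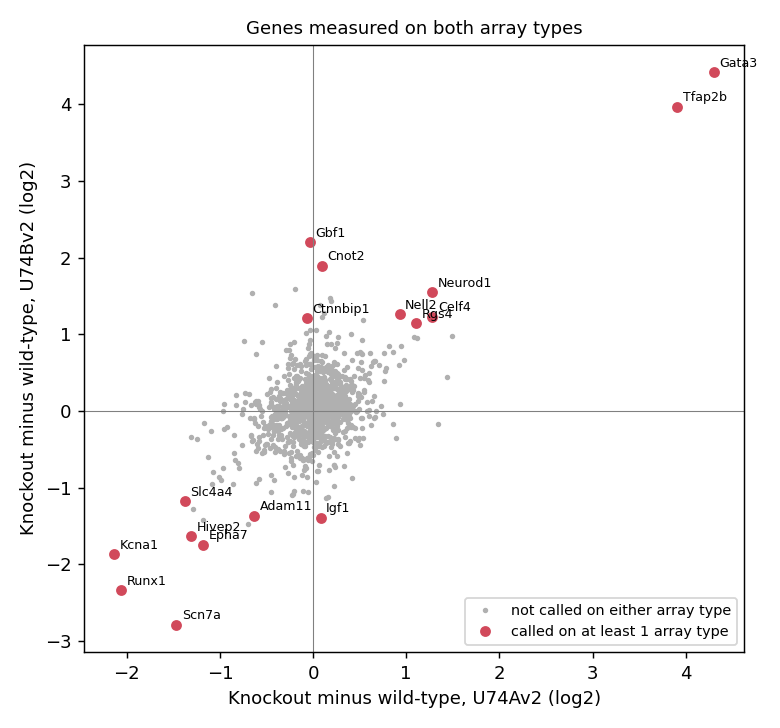
Knockout minus wild-type log2 difference of the 1121 genes tested on both array types, U74Av2 on the horizontal and U74Bv2 on the vertical axis; each point is a gene and red points are the 17 genes called on at least 1 type. Gata3 lies at 4.31 and 4.42, and Gbf1 at -0.03 and 2.20.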

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

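The tests of cross-hybridization and of the share of neurons were chosen after the results had been seen, and the 2 tests against the 18S signal before. The 18S ribosomal RNA probe sets, which no comparison used, were higher in knockout than in wild-type, 2.48-fold among the number 1 arrays and 1.90-fold among the number 2 arrays.

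The called changes of Gata3, Sst, Rgs10 and the other genes on U74Av2 could reflect a difference in RNA or labelling that the 18S signal tracks. The difference between array numbers was scaled to the 18S difference between knockout and wild-type. It predicted a median share of 0.0124 of the knockout changes of the 19 called probe sets (95% bootstrap interval, resampling probe sets, 0.00240 to 0.0230). These probe sets were called by a fit that counts differences between numbers as spread, so their selection itself favoured a small share. The test therefore cannot speak for probe sets that were not called. The 18S signal differed 10.1- to 13.2-fold between numbers, more than between knockout and wild-type. A cause that follows it would have moved the called probe sets more between numbers than between genotypes. At the median they did not move so, which argues against such a cause for these 19 alone. A labelling difference that the 18S signal does not track stays open. Cross-hybridization of single probe sets stays open too. Of 6 other tested probe sets of the called genes 83.3% moved in the called direction (exact 95% interval 35.9% to 99.6%), and 5 of the 6 were called themselves, for Gata3, Tfap2b, Runx1, Kcna1 and Rgs10, while Gal's other probe set stood at 0.16. For the remaining genes no other probe set was tested. The loss of Brn3a, the biological explanation the design gives, is a hypothesis with these left open.

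The small rise of cell cycle genes could come from a lower share of neurons. The test assumed that this would raise the markers of all other cell types alike, which need not hold for cells carried along in a dissection. Over 97 genes of 7 non-neuronal lists the median was 0.13 (95% bootstrap interval 0.02 to 0.21), below the cell cycle median (difference -0.24, interval -0.37 to -0.11, and -0.34 in a version run before this one that left out the connective tissue list), as it was against heterozygotes (-0.38, interval -0.51 to -0.21). These intervals come from resampling genes on the same arrays, with genes taken as independent. They hold no variation between pools, so they do not tell whether the difference would hold in other ganglia. On these arrays alone, the difference argues against a lower share of neurons as the whole cause, though the positive median leaves room for a part. The connective tissue list (0.26, interval 0.19 to 0.36) was not set apart from the cell cycle list (0.37, interval 0.28 to 0.43) against wild-type. Against heterozygotes it was (0.15, interval 0.03 to 0.29, and 0.44, interval 0.31 to 0.57), and there the connective tissue list did not pass (camera adjusted p = 0.149). The 18S signal predicted a median rise of 0.0282 (interval -7.8e-05 to 0.0478), well below the observed one. More cycling cells, in connective tissue or elsewhere, and delayed differentiation in the knockout stay open and untested, and with an estimated correlation the list has an adjusted p of 0.208.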

How the results depend on the processing

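No result past the threshold, before or after a change of setting, reversed its direction. Below the threshold some did: the neuronal cytoskeleton list in knockout against wild-type was up by camera and down by fry on U74Av2 and the other way on U74Bv2, and camera and fry also differed for central nervous system markers in heterozygote against wild-type on U74Av2 and neurotrophin receptors in knockout against heterozygote on U74Bv2. With the block, on U74Bv2, the median of the glia list against wild-type went from 0.01 to -0.13 and that of ion channels in heterozygote against wild-type from 0.10 to -0.00192. The causes of the changes below were not tested unless fewer genes or arrays entered the fit. Of the values followed per gene 4729 stayed on their side of the threshold, 199 lost and 34 gained the call and 185 without a call moved by more than their standard error, and of the list values 428 stayed, 49 lost and 8 gained it. Of the counts and correlations 169 stayed close and 79 moved. Knockout against wild-type on U74Av2 (19 called) gave 11 with the filter at the 60th percentile, 58 with a fold rule in place of a test, 381 at an unadjusted p under 0.05 and 0 to 15 with 1 array left out. On U74Bv2 (104) it gave 40 without an intensity trend, 21 without a filter, 164 with only the 2 genotypes in the fit, 183 with the fold rule, 834 unadjusted and 115 to 178 with 1 array left out, and without the wild-type array no comparison with wild-type could be made. Knockout against heterozygote on U74Av2 (14) gave 8 with the higher filter, 65 with the fold rule, 391 unadjusted and 0 to 11 with 1 array left out, and on U74Bv2 (127) 81 without a trend, 54 without a filter, 720 unadjusted and 130 to 188 with 1 array left out. Heterozygote against wild-type gave 5 with the fold rule and 52 unadjusted on U74Av2, and 52 with the fold rule, 2 with only the 2 genotypes, 283 unadjusted and 0 to 10 with 1 array left out on U74Bv2. Knockout against all others gave 42 with the higher filter and 17 to 42 with 1 array left out on U74Av2 (65), and 112 to 202 on U74Bv2 (218). With the replicate number as a block the counts were 130 and 216 for knockout against wild-type, 129 and 317 against heterozygote, 0 and 7 for heterozygote against wild-type and 266 and 231 for knockout against all others, on U74Av2 and U74Bv2. The differences between numbers correlated between genotypes by 0.619, 0.571 and 0.533 on U74Av2 and by 0.103 on U74Bv2, with fewer pairs than the preset rule for pairing asked for. Shifted gene lists fell to 0 in every comparison with an estimated correlation. Camera then uses the residual degrees of freedom, 3 on U74Av2 and 2 on U74Bv2, so a list can scarcely pass. The loss of lists with that correlation therefore decides nothing for or against them. On U74Av2 that correlation was below 0 for ion channels (-0.011), synaptic vesicle genes (-0.052), connective tissue markers (-0.0046) and calcium-binding proteins (-0.094). Correlation between their members therefore does not account for the loss of those lists. It was 0.064 for cell cycle, and its part in the loss of that list was not measured. Among the shifted lists on U74Bv2 it was below 0 for ion channels alone (-0.018). In knockout against wild-type they numbered 3 on U74Av2 (5) with the higher filter and with fry, and 1 to 6 with 1 array left out, and on U74Bv2 (4) 2 with the higher filter, 0 with fry and 4 to 5 with 1 array left out. Against heterozygote they numbered 1 to 5 on U74Av2 (3) and 1 to 4 on U74Bv2 (4) with 1 array left out, and 1 on U74Bv2 with the higher filter. In heterozygote against wild-type on U74Av2 (0) they numbered 1 with all probe sets of a gene, with fry, with the higher pseudocount and with the replicate block, 2 with the higher filter and with a pseudocount of 1, and 0 to 4 with 1 array left out. The 3 lists that passed by fry in knockout against wild-type on U74Av2 were not all among the 5 of the main test. They were synaptic vesicle genes and neurotrophin receptors (fry adjusted p = 0.0351 each) and calcium-binding proteins (8.92e-04). Neurotrophin receptors had not passed by camera. Cell cycle (fry adjusted p = 0.0521), connective tissue markers (0.0644) and ion channels (0.166) did not pass by fry. Pearson's r between array types (0.50) was 0.354 without a filter, 0.390 with a pseudocount of 1 and, with 1 array left out, 0.453 (knockout 1) and 0.345 (knockout 2) for those of U74Av2, 0.405 and 0.431 for those of U74Bv2, 0.418 and 0.445 for the wild-type U74Av2 arrays and little changed for the heterozygotes.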

Other observations

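The test of gene dosage was chosen after the result had been seen. Some called genes regulate G-protein or Ras signalling. They were picked after their values were seen, were not tested as a list and did not share a direction. In knockout against wild-type Rgs10 (-3.30), Rasa4 (-2.20), Diras2 (-2.55) and Rgs7bp (-2.28) fell, while Rgs4 rose on U74Bv2 (1.15, adjusted p = 0.0403) and stood at 1.11 on U74Av2 (adjusted p = 0.597).

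A candidate explanation for the heterozygote's nearness to wild-type on U74Av2 is that these transcripts do not follow the number of functional Pou4f1 alleles in proportion. Proportional dosage would put the heterozygote's signal halfway. On the log2 scale that point lies nearer wild-type for falling and nearer knockout for rising transcripts, so the shares have no single expected value. The median share of the knockout change over the 19 probe sets called on U74Av2 was 0.0599 (95% bootstrap interval 0.0165 to 0.131, resampling probe sets on the same arrays). The largest share was 0.276, for the rising Vegfd. Among falling transcripts Shc1 had the largest (0.155), with signals of 905 and 906 in heterozygotes against means of 1109 in wild-type and 282 in knockout. These values argue against proportional dosage for these genes but leave a small shift toward the knockout. The Pou4f1 signal in heterozygotes (2196 and 3570, against 3313 in the 1 wild-type array) was itself not measurably lower, so the product's level is open.

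Replicate number 1 differed from number 2 in 1820 of 7453 probe sets on U74Av2 (limma adjusted p under 0.05 with genotype in the fit), 813 higher in number 1 and 1007 in number 2, and in 15 of 7446 on U74Bv2. The Xist signal on U74Av2, which follows the share of female embryos in a pool, was 1223 and 1336 in wild-type, 1363 and 380 in heterozygote and 825 and 1815 in knockout arrays. On U74Bv2 it was 168 in wild-type, 38.4 and 544 in heterozygote and 303 and 372 in knockout arrays, so that the heterozygote numbers were ordered the other way. Kdm5d, a gene of the Y chromosome, stood there at 336 and 140 in heterozygotes, from a family probe set. On U74Av2 the Y-linked Uty stood at 15 and 140 in heterozygotes and Eif2s3y, from a family probe set, at 21.6 and 166.5. Kdm5d there went the other way (30 and 17), and all of these U74Av2 probe sets were too dim to be tested. Same-numbered heterozygote arrays of the 2 types may thus not hold the same pool.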
